A study of Mus musculus with 8 samples.

How the data were processed

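Dendritic cells grown from mouse bone marrow were profiled on 8 Affymetrix MOE430A arrays, 1 array for each combination of genotype (VDRwt or VDRmut), VD3 (with or without) and TNFa (with or without). Per the labels, the VDRmut mice carry a vitamin D receptor whose DNA-binding domain is deleted, VD3 is 1,25-dihydroxyvitamin D3 given at 1e-06 M for 30 min before the cytokine, and TNFa was given at 50 ng/ml for 4 h on day 7 of differentiation. Array groups were taken from the sample titles.

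The deposited tables hold, per the file headers, a linear signal intensity and a detection call (Present, Marginal or Absent) for each of 22690 probe sets, and the submitters' processing notes name MAS5 without a version. Each array's intensities had a 2% trimmed mean of 200.1, so the arrays shared 1 scale before deposit. A series matrix holds the same intensities with more digits, and its values differed from the tables by at most 0.05. The experiment records deposited beside the tables give a scan day and a fluidics protocol for the 4 VDRwt arrays, and these fields are empty for the VDRmut arrays.

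Signals were rescaled to a common trimmed mean (factors 0.99997 to 1) and put on the log2 scale, after 3 signals listed at 0 were raised to 0.1. The 64 control probe sets were left out of the tests, and probe sets with a Present call on at least 2 of the 8 arrays were kept, which left 12832. Between 46.45% and 51.54% of probe sets were called Present on an array. Genes were named from the platform annotation supplied with the series: 20393 probe sets had 1 gene symbol, 691 had several and 1606 had none, and 20364 of the first kind matched a current RefSeq symbol of the GRCm38.p6 assembly with 0 changed. No gene was named from a probe set with several symbols. Where a gene had several probe sets the brightest was used, which gave 7578 genes. Apart from that symbol reference, no genome build is named in the sources used here, so no coordinates are given.

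Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The planned model held genotype, TNFa and a VD3 effect in each genotype (3 residual degrees of freedom). A further coefficient gave the TNFa effect by genotype (2 residual degrees of freedom). The change of the TNFa response by VD3 within a genotype rests on 1 array per condition, so it was planned as a size without a test. A second model, chosen after the data were seen, held genotype, VD3, TNFa without VD3 and TNFa with VD3 (3 residual degrees of freedom), and its contrast between the TNFa responses is called VD3 by TNFa. That model treats the genotypes as replicates for each treatment. Errors given as ± are limma standard errors of log2 changes. The labels do not say that the arrays come from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical.

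Before the data were examined, 24 lists with 661 gene entries were written down from general knowledge of dendritic cells, TNFa and vitamin D, with markers of other cell types among them. Each was tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated from the data. Counts of list members past the threshold are given over all probe sets and, where stated, adjusted over the list alone. List medians within 1 genotype were set against 10000 random lists of the same size matched on mean expression. Ranges given for random lists run from their 2.5th to their 97.5th percentile.

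Genes named in the text followed a rule fixed before the data were examined: Vdr, Cyp24a1 and the vitamin D response list; for TNFa the 12 highest and 8 lowest log2 changes among calls with 1 direction in all 4 array pairs; for VD3 in VDRwt the calls or, where too few passed, genes of at least 1 in log2 size in both VDRwt pairs and under 0.5 in both VDRmut pairs; genes whose VDRwt TNFa response shrank or grew most with VD3; the 5 highest and 5 lowest genotype calls; and up to 4 members of each list. The extreme genes of the second model and the genotype genes of smallest p were added by the same kind of rule after the data were seen. Where a gene was not called Present on any array of the dimmer side, its change is given as at least N-fold, computed against the higher of its own signal and the lowest Present signal of each array. These lowest signals were 3.1 to 8.4, below Absent signals such as 36.9 for Cyp24a1 on the VDRwt TNFa array. A size given as at least N-fold is therefore an estimate and not a strict lower bound. Signals are given instead where both arrays of a pair were not called Present.

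The fits were tested on simulated data with 12832 probe sets, of which 100 were given a log2 change of 1, 50 a change of 2 and 50 a change of 4. For the TNFa effect, 28% of log2 changes of 1, 86% of changes of 2 and 100% of changes of 4 were recovered. For VD3 in VDRwt the shares were 4%, 56% and 94%. For TNFa without VD3 they were 25%, 98% and 96%, and for TNFa with VD3 31%, 96% and 100%. For VD3 by TNFa they were 5%, 56% and 98%, and for genotype 25%, 96% and 100%. For VD3 by genotype they were 0%, 26% and 84%, and for TNFa by genotype 1%, 10% and 88%. The number of arrays therefore limits what size of VD3 effect can pass. The same fits gave 13 false calls for the TNFa effect, 5 for VD3 in VDRwt and 19 for TNFa without VD3. They gave 16 for TNFa with VD3, 8 for VD3 by TNFa and 7 for genotype. VD3 by genotype had 5 and TNFa by genotype 8. For each comparison, false calls were a larger share of the simulated calls than the adjusted p threshold. The counts of calls below may therefore hold more false calls than that threshold implies. Alternatives were deposited scaling, quantile normalization, a floor of 50, a stricter or no Present filter, eBayes without a trend, the series matrix, other models, fits within a genotype, other sizes, and leaving out each array. Added after the data were seen were a block for scan day (which coincides with TNFa in VDRwt, so the TNFa effect is then measured in VDRmut), the second model, and fits without the arrays that stood apart in their control probe sets. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.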

Results

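The series asks how vitamin D changes the activation of dendritic cells by TNFa, and whether the response needs a vitamin D receptor with its DNA-binding domain. Dendritic cells are the antigen-presenting cells that TNFa drives from an immature, antigen-capturing state to a mature one. RNA from bone marrow-derived dendritic cells was measured on 8 arrays: untreated, VD3, TNFa and VD3+TNFa cells of VDRwt mice and the same 4 conditions of VDRmut mice. Each condition has 1 array, so no condition has replicates of its own, and every tested effect was averaged over pairs of arrays that share a treatment or a genotype.

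The receptor itself was measured first. The Vdr probe set gave signals of 93.7 (untreated), 185.7 (VD3), 33.2 (TNFa) and 104 (VD3+TNFa) in VDRwt and 12.4, 67.2, 6.3 and 43.7 in the same order in VDRmut. It was lower in VDRmut in each of the 4 matched pairs, with a log2 change of -2.01 ± 0.29 (SE), but an adjusted p of 0.653. Where this probe set lies relative to the deleted part is not given, so it checks the genotype only loosely. Cyp24a1, the vitamin D 24-hydroxylase and a standard receptor target, was called Present on 2 arrays, VDRwt with VD3 (80.3) and VDRwt with VD3+TNFa (59.5). Its other signals were 2.2 and 36.9 in VDRwt and 7 to 28.2 in VDRmut.

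Control probe sets differed between arrays. The 5' probe set of the 18S ribosomal RNA control read 9028 on the VDRwt TNFa array and 6847 on the VDRmut TNFa array, against 3.5 to 224 on the other 6. Its 3' probe set read 8511 and 7129 on that pair, 1121 on the VDRwt VD3+TNFa array and 50.5 to 227.3 on the rest. The ratio of the 5' to the 3' beta-actin probe set was 0.444 on the VDRmut untreated array and 0.449 on the VDRmut VD3+TNFa array, against 0.781 to 0.889 on the others. The 5' to 3' ratio of Gapdh was 1.15 and 1.28 on that pair, and 1.17 to 1.38 on the others. The VDRwt arrays without TNFa were scanned on another day than those with it. The VDRwt VD3+TNFa array was also run with another fluidics protocol than the other VDRwt arrays, so protocol and treatment cannot be told apart on it.

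**Figure D1:**
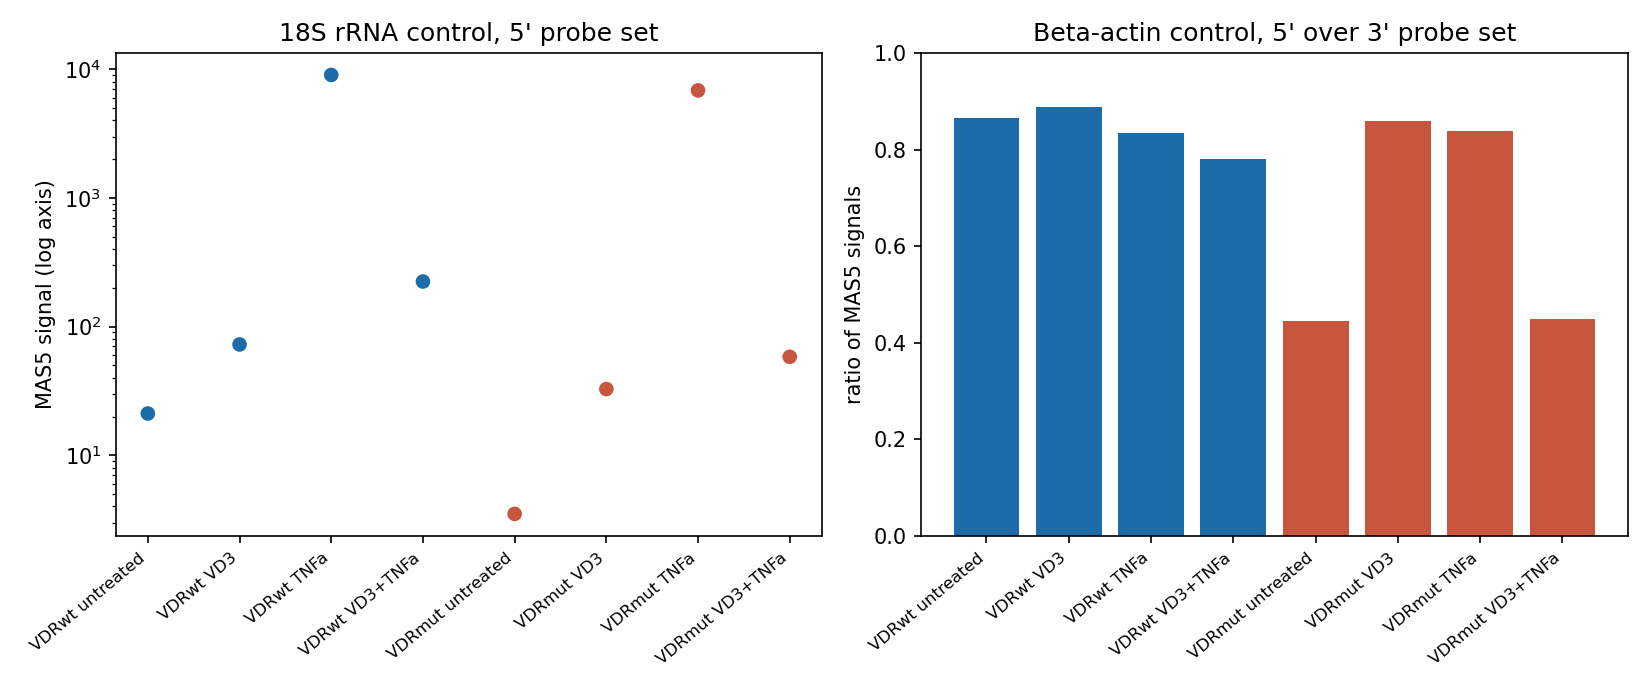
Signal of the 5' 18S rRNA control probe set (left, log axis, MAS5 signal) and the ratio of the 5' to the 3' beta-actin control probe set (right, bars from 0) on each of the 8 arrays, VDRwt in blue and VDRmut in red. Both TNFa arrays without VD3 sit at 9028 and 6847 for 18S, and the actin ratio is 0.444 and 0.449 on the VDRmut untreated and VD3+TNFa arrays.

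TNFa changed a set of genes in both genotypes, with VD3 and without. Cxcl2, a neutrophil-attracting chemokine, rose 9.18-fold (log2 3.20 ± 0.37, adjusted p = 0.0422), Nfkbiz, an inducible nuclear IkB protein, 4.58-fold (2.20 ± 0.20, adjusted p = 0.0319) and Clec4e, a receptor for mycobacterial glycolipid, 4.11-fold (2.04 ± 0.21, adjusted p = 0.0393). Cd207, the Langerhans cell lectin langerin, was also called, but it was Present on both arrays with TNFa alone (319.5 and 651.9) and Absent on the other 6, so no change with VD3 is shown above background. The apoptosis regulators Pmaip1 (3.77-fold), Cflar (2.85-fold) and Birc3 (2.68-fold) rose, as did Fscn1 (3.08-fold), an actin-bundling protein of mature dendritic cells, Uap1, Map3k12, Fstl1 and Rpl27a (3.12- to 3.65-fold) and Ccrl2 (at least 3.17-fold). The cyclin Ccnd3 fell 2.49-fold. Oas3, an antiviral oligoadenylate synthetase, was called lower, from 414 to 52.2 (Absent) without VD3 and from 540 to 141.1 (Absent) with it in VDRwt, and was Absent on all 4 VDRmut arrays. The signals of all of these moved in 1 direction in each of the 4 array pairs.

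For the TNFa effect over both VD3 states, 29 of 12832 probe sets passed, 26 higher and 3 lower. At an unadjusted p under 0.05 there were 2559, against 641.6 by chance. Of the NF-kB target list 3 of 32 members were called higher (13 adjusted over the list alone), with a median log2 change of 0.76, and of the dendritic cell maturation list 1 of 34 (19 adjusted over the list alone), with a median of 0.78. Camera gave adjusted p = 5.2e-14 for each and adjusted p = 0.64 with an estimated correlation. The cytokine list shifted up (median 0.44, 0 of 19 called, 8 higher and 1 lower adjusted over the list alone, adjusted p = 0.0069), as did the heat shock and stress list (median 0.27, 0 of 29 called, 2 higher and 2 lower over the list alone, adjusted p = 0.035), each with adjusted p = 0.64 with an estimated correlation. The cell cycle list (median -0.40, 1 of 33 called lower, 5 over the list alone, adjusted p = 0.0024) and the neutrophil marker list (median -0.70, 0 of 14 called, 2 lower over the list alone, adjusted p = 0.018) shifted down, each with adjusted p = 0.74 with an estimated correlation. The 29 calls fell to between 0 and 6 when any 1 array was left out, and to 0 with a signal floor of 50 or without both VDRmut arrays of low actin ratio. They also fell to 0 with scan day as a block, which leaves the TNFa effect to VDRmut. This model gives TNFa the same effect with and without VD3, so any difference between these responses enters its error. In the same model 1313 probe sets passed once both arrays with TNFa alone were left out, which leaves only the TNFa pairs with VD3. That reduced fit has 1 residual degree of freedom, the difference between these TNFa pairs, so its count cannot be set beside the 29. Over all 8 arrays, the fit of the TNFa effect with VD3 called 103.

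Fitted apart, a step chosen after the data were seen, the TNFa responses without and with VD3 were of different size. Without VD3, Il12b, the p40 subunit of interleukin-12 and interleukin-23, rose 26.9-fold (log2 4.75 ± 0.25, adjusted p = 4.13e-05) from 78.2 to 2573 in VDRwt and from 103.7 to 2273 in VDRmut. Cxcl1, a neutrophil-attracting chemokine, rose at least 48.1-fold, and Bex1 46.5-fold. The costimulatory receptor Cd40 rose by 4.17 ± 0.40 on the log2 scale (adjusted p = 0.00105). Cd207 (at least 14.7-fold), Grasp (at least 11.6-fold), A630072M18Rik (at least 21.7-fold), Gem (at least 6.91-fold), Net1 (14.6-fold) and Malat1 (15.9-fold) were the others among the 10 largest fitted rises. For Malat1 the log2 change was 1.86 in VDRwt and 6.12 in VDRmut, where the untreated array, of low actin ratio, read 32.4 (Absent). The largest falls were those of Olfm1 (at least 94.4-fold, adjusted p = 3.42e-05), the leukotriene B4 receptor Ltb4r1 (at least 42.5-fold), the carbonic anhydrase Car4 (42.7-fold; -5.42 ± 0.25), Rnase2a (at least 33.7-fold), Lsr (247 to an Absent 10.5 in VDRwt, Absent throughout in VDRmut), Klk1b1 (12.6-fold), arginase Arg1 (at least 12.5-fold) and Slfn1 (12.5-fold).

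**Figure D2:**
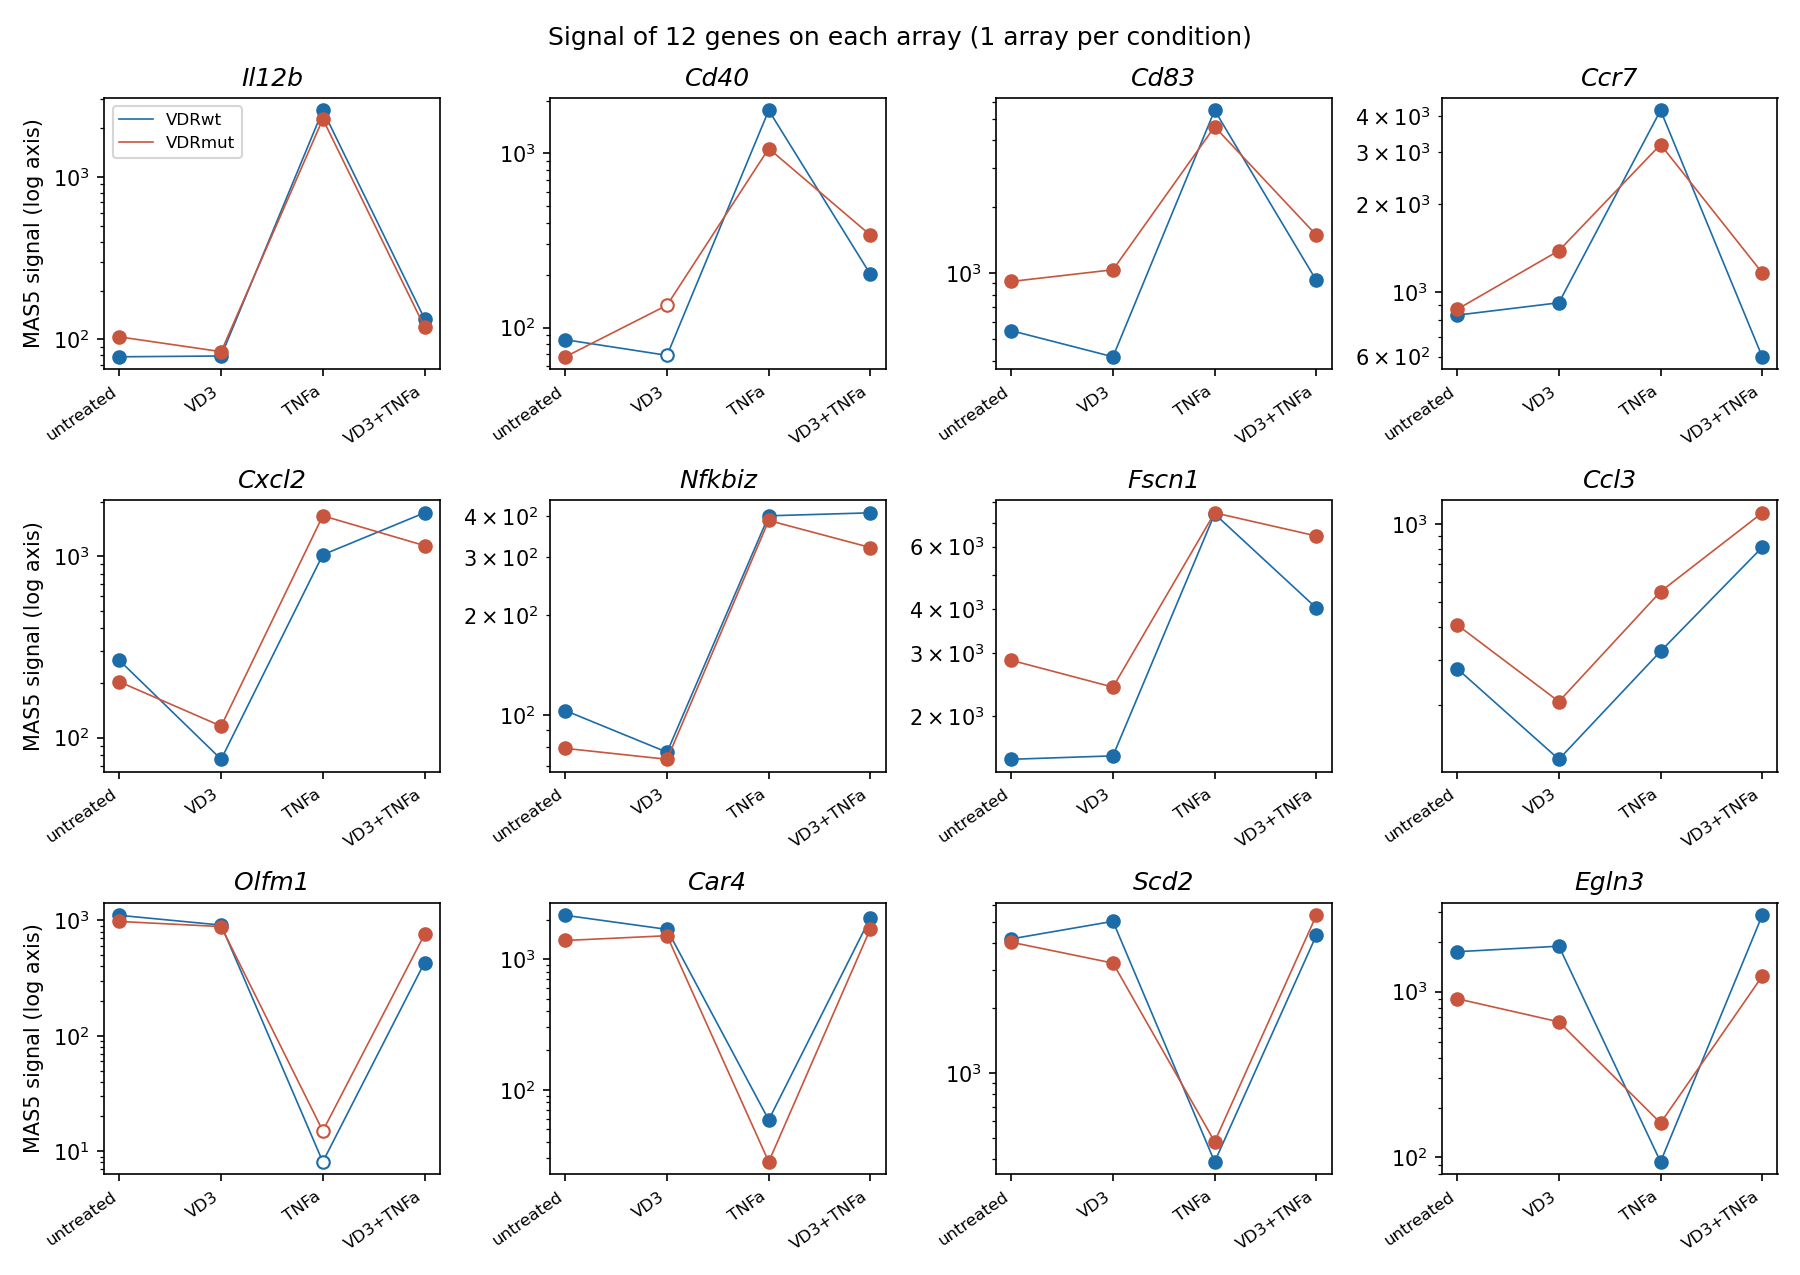
MAS5 signal (log axis) of 12 genes on each of the 8 arrays, VDRwt in blue and VDRmut in red; filled points were called Present, open points were not, and lines join the arrays of a genotype. Il12b reads 2573 and 2273 with TNFa alone and 134.2 and 119.4 with VD3+TNFa, while Cxcl2 reads 1018 and 1670 with TNFa alone and 1734 and 1144 with VD3+TNFa.

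Of 12832 probe sets, 1418 passed for the TNFa effect without VD3, 726 higher and 692 lower. On the NF-kB target list 19 of 32 members rose (22 adjusted over the list alone; median log2 1.3, adjusted p = 3.9e-15), among them Birc2 (4.5-fold), Nfkbiz (4.36-fold), Dusp1 (4.24-fold) and Vcam1 (at least 4.1-fold). On the dendritic cell maturation list 21 of 34 rose (23 over the list alone; median 1.3, adjusted p = 3.9e-15), among them Serpinb9 (7.69-fold), the costimulatory ligand Cd70 (at least 7.65-fold) and Cd83 (7.1-fold), a surface marker of mature dendritic cells. On the cytokine list 6 of 19 rose and 1 fell (8 and 3 over the list alone; median 0.84, adjusted p = 0.0023), with Tnfsf4, the OX40 ligand, at 8.31-fold, Igf1 at 7.33-fold and Il6 at 4.9-fold. These 3 lists each had adjusted p = 0.28 with an estimated correlation.

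The same pair of TNFa arrays had lower signals for antigen uptake, metabolism and division. Of the innate and endocytic receptor list 13 of 33 fell and 1 rose (15 and 5 adjusted over the list alone; median -0.53, adjusted p = 0.00016, and adjusted p = 0.62 with an estimated correlation), with the C-type lectins Mgl2 (9.52-fold) and Clec10a (at least 5.87-fold) and the integrin Itgam (6.89-fold) among them. Of the glycolysis list 9 of 20 fell and 1 rose (12 and 1 over the list alone; median -1.0, adjusted p = 2e-05, and adjusted p = 0.59 with an estimated correlation): the prolyl hydroxylase Egln3 fell 10.2-fold, pyruvate kinase Pkm 4.46-fold and Bnip3, a mitophagy receptor, 4.02-fold, while Pfkfb3, which makes an activator of phosphofructokinase, rose 7.66-fold. Of the cholesterol and lipid list 7 of 28 fell and 3 rose (9 and 5 over the list alone; median -0.60, adjusted p = 0.024, and adjusted p = 0.59 with an estimated correlation), with the desaturase Scd2 (9.43-fold), the fatty acid synthase Fasn (at least 7.96-fold), Dhcr7 (at least 5.08-fold) and Fdps (4.22-fold) lower. The oxidative phosphorylation list shifted by a median of -0.42 with 2 of 33 members lower, Ndufa5 (2.12-fold) and Cycs (1.78-fold) (1 over the list alone; adjusted p = 0.00034, and adjusted p = 0.59 with an estimated correlation). Of the cell cycle list 7 of 33 fell (11 over the list alone; median -0.70, adjusted p = 2.8e-05, and adjusted p = 0.62 with an estimated correlation), among them the helicase subunit Mcm2 (2.68-fold) and the ribonucleotide reductase subunit Rrm2 (2.55-fold). The neutrophil marker list fell in 7 of 14 members (8 over the list alone; median -1.4, adjusted p = 0.0001, and adjusted p = 0.46 with an estimated correlation), with Cd177 (at least 5.07-fold), lactoferrin Ltf (4.11-fold) and lipocalin Lcn2 (3.45-fold). Every one of these changes is measured on the arrays of high 18S signal, 9028 and 6847. The 1418 calls of the TNFa effect without VD3 became 365 without the VDRwt TNFa array, 810 without the VDRwt untreated array and 942 without the VDRmut TNFa array, 341 with scan day as a block, where TNFa and scan day coincide in VDRwt, and 512 with a signal floor of 50.

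With VD3, 103 probe sets passed for TNFa, 82 higher and 21 lower. Cxcl2 rose 15.0-fold (3.91 ± 0.34, adjusted p = 0.00462), Serpinb2, a plasminogen activator inhibitor, 6.99-fold, the chemokine Ccl3 5.96-fold (2.57 ± 0.21, adjusted p = 0.00446), the long pentraxin Ptx3 at least 5.7-fold, Il1a 4.82-fold, Snrnp40 4.83-fold and Nfkbiz 4.81-fold. Clec4e (4.67-fold), the cytokine signalling suppressor Socs3 (3.54-fold) and the sterol synthesis enzymes Fdft1 (3.94-fold) and Hmgcs1 (2.22-fold) also rose. The interleukin-6 receptor chain Il6ra (at least 9.15-fold), Rgs2 (3.65-fold) and B3gnt8 (3.51-fold) were among the largest falls of called genes, with Akap9, which was Absent on both VDRwt arrays with VD3. The NF-kB target list had 3 of 32 members higher, Nfkbiz, Cflar and Birc3 (12 adjusted over the list alone; median 0.38, adjusted p = 6.1e-06, and adjusted p = 0.64 with an estimated correlation). The dendritic cell maturation list had 1 of 34, Fscn1 (8 higher and 1 lower over the list alone; median 0.53, adjusted p = 5.5e-06, and adjusted p = 0.81 with an estimated correlation), and the cytokine list had 1 of 19, Il1a (2 over the list alone; median 0.17, adjusted p = 0.016, and adjusted p = 0.64 with an estimated correlation). The count of 103 was fragile. It was 0 without the VDRwt VD3+TNFa array, 2 without the VDRwt VD3 array, 2 without the VDRmut VD3+TNFa array and 6 without the VDRmut VD3 array. It was 692 without the VDRwt untreated array, 681 without the VDRmut untreated array and 1 with a signal floor of 50 or scan day as a block. Of the calls with VD3, 37 of the higher ones were also among the 726 (4.64 by independent lists) and 6 of the lower ones among the 692 (1.13), in a fit where both contrasts share 1 error estimate.

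The difference between these TNFa responses, VD3 by TNFa, passed for 227 probe sets, 123 positive and 104 negative. Of these 199 were also called for TNFa without VD3, 93 higher and 106 lower, and each difference ran against the response without VD3. The difference subtracts that same response in the same fit, so its direction in these 199 follows largely from the choice. For 72 of the 93 and 80 of the 106 the fitted response with VD3 had the opposite sign. Over the 726 higher probe sets the median log2 TNFa change was 1.46 without VD3 and 0.354 with it, and over the 692 lower ones -1.27 and -0.228. Because these sets were chosen on the TNFa arrays without VD3, part of that difference follows from the choice. With VD3+TNFa, Il12b reached 134.2 in VDRwt and 119.4 in VDRmut, a response smaller by 4.11 ± 0.35 on the log2 scale (adjusted p = 0.00271). The chemokine receptor Ccr7, which guides dendritic cells to lymph nodes, rose 2.33 and 1.87 in log2 without VD3 and changed by -0.61 and -0.25 with it in VDRwt and VDRmut (difference -2.53 ± 0.43, adjusted p = 0.0284). Among called genes, the largest negative differences after Cxcl1 and Bex1 were those of Il12b, Pnkd, Gsap, 2610528A11Rik, 4930520O04Rik and Net1 (-4.11 to -3.42), and the largest positive ones those of Olfm1, Car4, Rnase2a, Arg1, Egln3, the adhesion protein Cdh1, Aldoc and Scd2 (5.91 to 3.50); several of these sizes depend on signals not called Present.

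By list, the difference called VD3 by TNFa was negative for NF-kB targets (median -0.91, 1 of 32 called, Gadd45b, 11 adjusted over the list alone, adjusted p = 9.7e-05) and dendritic cell maturation (median -0.73, 2 of 34, 11 over the list alone, adjusted p = 1.9e-05). It was positive for innate and endocytic receptors (0.41, 4 of 33, 9 over the list alone, 1 of opposite sign, adjusted p = 1.9e-05) and glycolysis (1.1, 4 of 20 positive and Pfkfb3 negative, 11 and 1 over the list alone, adjusted p = 2.3e-05). It was also positive for neutrophil markers (0.77, 1 of 14, 6 over the list alone, adjusted p = 0.00054), oxidative phosphorylation (0.44, 1 of 33, 2 over the list alone, adjusted p = 0.0014), cell cycle (0.34, 0 of 33 either way, adjusted p = 0.0021) and cholesterol and lipid genes (0.53, 5 of 28 positive and 1 negative, 9 and 3 over the list alone, adjusted p = 0.0032). Each of these 8 lists had adjusted p = 0.62 with an estimated correlation. Among chemokines, the response of Ccl3 was larger with VD3 by 2.25 ± 0.30 (adjusted p = 0.0147), against -1.83 ± 0.31 for Ccl5 (adjusted p = 0.0284). The count of 227 ranged widely with the arrays used, from 7 without the VDRmut VD3 array through 18 (VDRmut VD3+TNFa), 27 (VDRwt VD3+TNFa), 44 (VDRwt VD3), 51 (VDRmut untreated) and 65 (VDRwt TNFa) to 470 (VDRwt untreated), and it was 10 with a signal floor of 50. The arrays with TNFa alone, on which each of these differences depends, are those of high 18S signal.

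**Figure D3:**
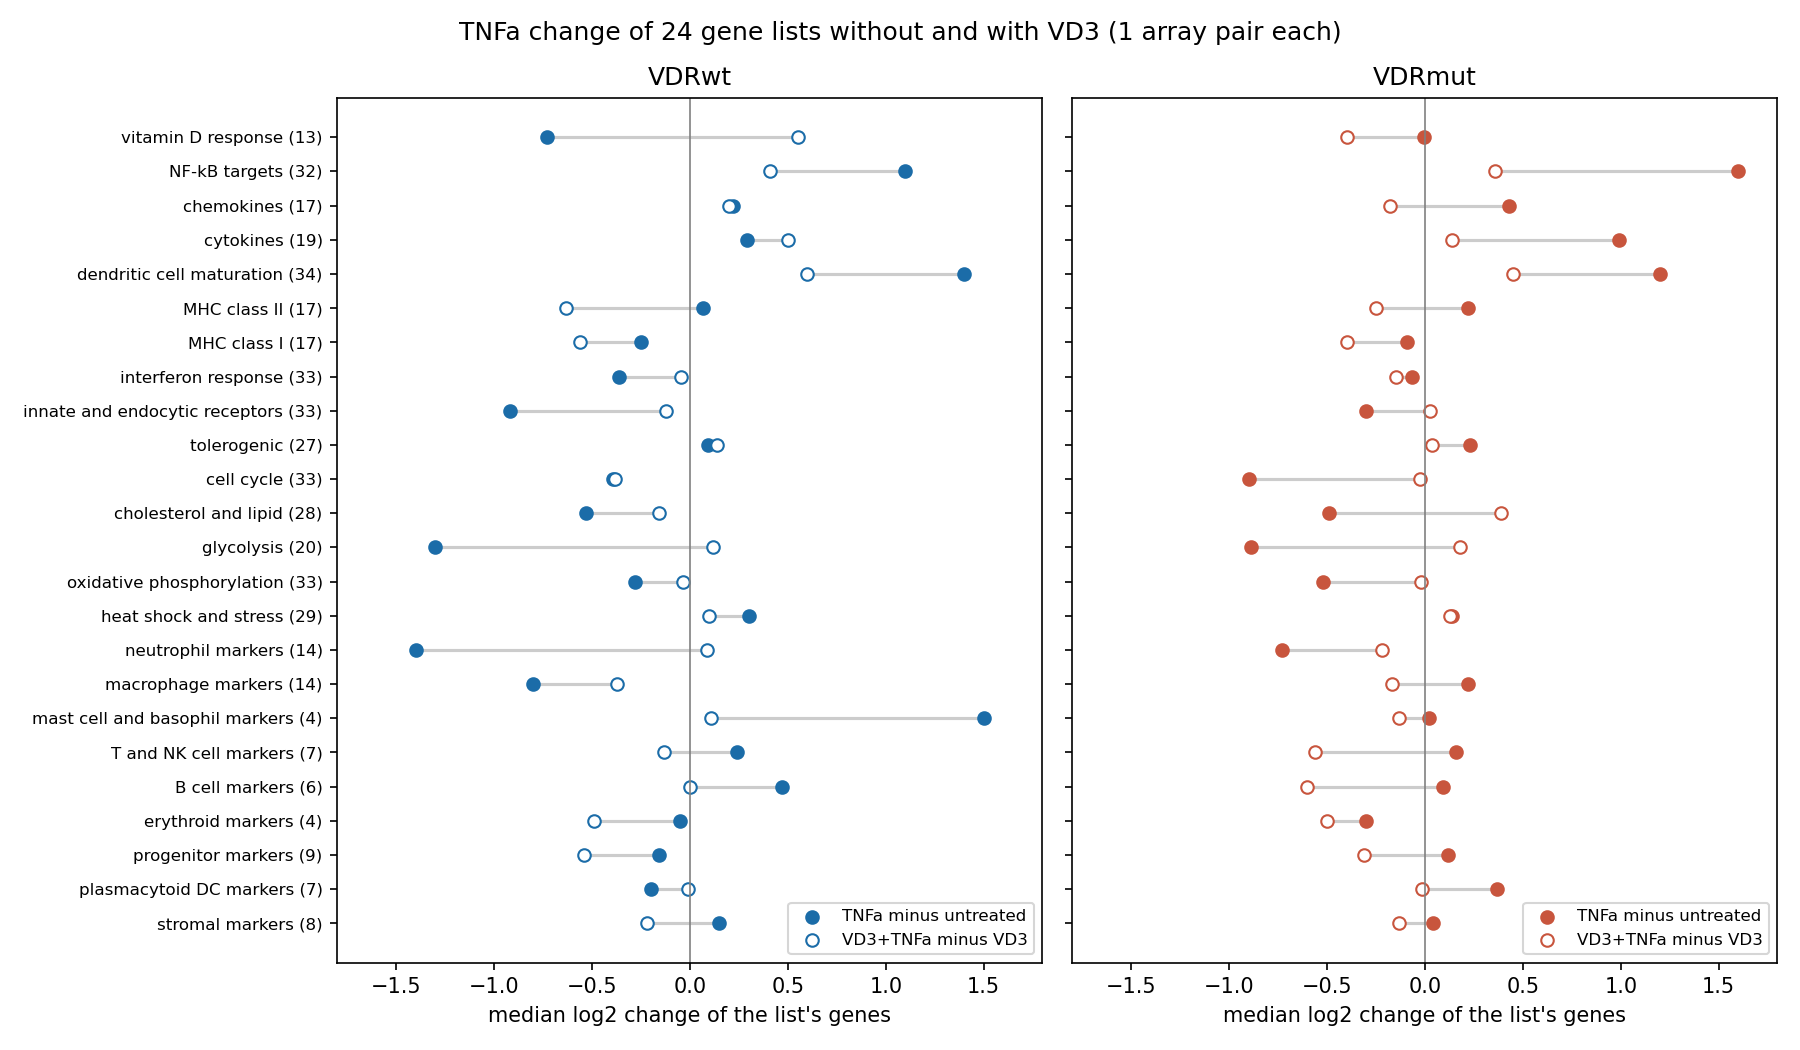
Median log2 TNFa change of each of 24 gene lists (number of measured genes in brackets) in VDRwt (left) and VDRmut (right), without VD3 (filled points) and with VD3 (open points), from 1 pair of arrays each. The NF-kB target list lies at 1.1 and 1.6 without VD3 and at 0.41 and 0.36 with it, and the glycolysis list at -1.3 and -0.89 without VD3 and at 0.12 and 0.18 with it.

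Within each genotype the change of the TNFa response by VD3 has 1 array per condition and no test. In VDRwt 2568 probe sets changed their response by at least 2-fold, and in VDRmut 4009 did. In both genotypes, 1167 did so in the same direction (408.4 if independent) and 165 in opposite directions. The VDRmut change sets the untreated and VD3+TNFa arrays, both of low actin ratio, against the other VDRmut arrays. Across the 12832 probe sets the change in VDRwt correlated with that in VDRmut with a Pearson r of 0.404 and a Spearman rho of 0.411. Probe sets are not independent replicates. The log2 TNFa change in VDRwt went from -3.50 to 0.28 for Itgam and from 3.37 to 0.44 for Tmem39a. A630072M18Rik (155.2), the ubiquitin ligase Fbxo32 (212.9) and Eno2 (129.9) were Present in VDRwt with TNFa alone and Absent on the other 3 VDRwt arrays. Lsr was Present without TNFa (247 and 279.8 with VD3) and Absent with it (10.5, and 133.5 with VD3). The response grew from 1.94 to 4.51 for Cxcl2, from 1.81 to 2.78 for Serpinb2 and from 1.43 to 2.07 for Clec4e. Mbd3, also named by the rule, was Absent on both VDRwt arrays with TNFa (32.9, and 11.8 with VD3), so no size is given.

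To keep the choice of genes apart from the measurement, TNFa genes were chosen in 1 genotype and measured in the other. A chosen probe set changed at least 2-fold in both pairs of that genotype, so those whose response VD3 ended there were left out. The 152 probe sets higher with TNFa in VDRmut had a median change of the VDRwt response with VD3 of -0.337 on the log2 scale, toward 0 (percentile 0 of 10000 matched random lists, of which the central 95% lay from -0.196 to 0.0988). That median was -0.147 with a signal floor of 50 and -0.125 at Present on 4 arrays (VD3 on TNFa genes, higher in VDRwt). The 57 lower ones had a response change of -0.331 toward 0 (percentile 0.07), and -0.82 with quantile normalization, -0.69 with the floor and -1.8 at a size of log2(3) (VD3 on TNFa genes, lower in VDRwt). The 249 probe sets higher with TNFa in VDRwt had a VDRmut change of -0.185, at percentile 62.8 of random lists, which turned to 0.0202 with quantile normalization and 0.0252 with the floor and was -0.538 at log2(3) (VD3 on TNFa genes, higher in VDRmut). The 209 lower ones had a change of 0.391, away from 0 (percentile 100), which was 0.233 at a size of log2(1.5) and 0.847 at log2(3) (VD3 on TNFa genes, lower in VDRmut). The VDRmut values rest on the untreated and VD3+TNFa arrays of low actin ratio.

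VD3 changed no probe set past the threshold in either genotype with limma, with 392 in VDRwt and 496 in VDRmut at an unadjusted p under 0.05 and 641.6 by chance. In VDRwt, 37 probe sets were at least 2-fold higher and 47 lower in both pairs, and in VDRmut 44 and 41. Of these 1 was higher and 6 were lower in both genotypes. Among those changed in VDRwt, 3 of the higher and 2 of the lower probe sets were flat in both VDRmut pairs. Of the genes among them, the actin-binding protein Ablim1 changed by 1.10 in log2 in the VDRwt pair without TNFa, and its pairs with TNFa include Absent signals. Psd3 was Present on both arrays with TNFa alone (137.9 and 94) and Absent on the other 6, so its VD3 changes depend on signals not above background. The receptor's own transcript was higher with VD3 by 1.32 ± 0.41 in VDRwt (adjusted p = 0.999). In VDRmut it read 67.2 (Present) and 43.7 (Absent) with VD3 and was Absent without it (12.4 and 6.3; adjusted p = 0.972). Averaged over both VDRwt pairs, Cyp24a1 was an estimated 5.42-fold higher with VD3, but the pairs were unlike. Without TNFa it read 80.3 with VD3 and 2.2 (Absent) without, and with TNFa 59.5 and 36.9 (Absent). Its other probe set was not called Present on any array. Hbegf, an epidermal growth factor ligand that was Present on the 2 VDRwt arrays with VD3 and on no other, was at least 3.87-fold higher. Neither gene passed the test (adjusted p = 0.999).

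Several lists shifted with VD3 although 0 of their members were called. In VDRwt the vitamin D response list was higher (13 of 27 genes measured, median 0.44, 9 positive, adjusted p = 0.00024), with Trem1, an innate receptor, at 2.08 ± 0.56 beside Cyp24a1 and Hbegf. Dendritic cell maturation was lower (median -0.76, 4 of 34 positive, adjusted p = 5.1e-11; Cd40 -1.71 ± 0.75, Serpinb9 -1.67 ± 0.59, Cd83 -1.48 ± 0.60), as were NF-kB targets (-0.28, 8 of 32 positive, adjusted p = 0.0017). Glycolysis was higher (0.88, 19 of 20 positive, adjusted p = 4.6e-09; Egln3 2.52 ± 1.12, Bnip3 1.84 ± 0.72), and so were innate and endocytic receptors (0.44, 27 of 33, adjusted p = 1e-05; Mgl2 1.85 ± 0.91, Itgam 1.77 ± 0.74), neutrophil markers (0.64, 11 of 14, adjusted p = 0.0022), interferon response genes (0.22, 24 of 33, adjusted p = 0.029) and cell cycle genes (0.19, 27 of 33, adjusted p = 0.035). With an estimated correlation each had adjusted p = 0.74, except cell cycle with adjusted p = 0.78. In VDRmut dendritic cell maturation was lower too (-0.31, 5 of 34 positive, adjusted p = 0.00098; Stat4 -1.03 ± 0.67, Serpinb6b -0.91 ± 0.50), and glycolysis (0.54, 17 of 20, adjusted p = 0.012) and cell cycle (0.38, 32 of 33, adjusted p = 3.1e-06; Mcm5 0.91 ± 0.33, Aurkb 0.85 ± 0.37) were higher, each with adjusted p = 0.90 with an estimated correlation. The vitamin D response list in VDRmut had a median of 0.16 (adjusted p = 0.24). Each VD3 effect averages a pair without TNFa and a pair with it, and the second contains an array of high 18S signal. The shifts came mostly from that second pair. In VDRwt the medians without and with TNFa were -0.14 and -1.2 for dendritic cell maturation, -0.13 and -0.56 for NF-kB targets and 0.26 and 1.4 for glycolysis. They were -0.046 and 0.85 for innate and endocytic receptors, -0.084 and 1.1 for neutrophil markers, 0.076 and 0.33 for interferon response, 0.31 and 0.81 for vitamin D response and 0.21 and 0.15 for cell cycle. In VDRmut they were -0.011 and -0.72 for dendritic cell maturation, 0.024 and 1.1 for glycolysis and -0.13 and 0.86 for cell cycle. For vitamin D response in VDRmut they were 0.39 and -0.092. Without TNFa this list was therefore no lower in VDRmut (0.39) than in VDRwt (0.31), and the genotypes differed only in the pair with TNFa. The VDRmut pair without TNFa includes the untreated array of low actin ratio. Il12b, of the cytokine list, changed by 0.02 and -4.26 in VDRwt and by -0.30 and -4.25 in VDRmut.

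No probe set passed for a difference in VD3 effect between genotypes (0 of 12832 with limma, 140 at an unadjusted p under 0.05) or in TNFa effect (0, with 158). On simulated data the fits recovered 26% of VD3 differences between genotypes of 2 on the log2 scale and 84% of those of 4, and 10% and 88% of such TNFa differences, so most differences of 2 would be missed. Without both arrays of TNFa alone, VD3 in VDRmut and VD3 by genotype had calls, while VD3 in VDRwt had none. The only VDRmut array without VD3 is then the untreated one, of low actin ratio. No VD3 effect in VDRmut is therefore read from these calls.

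Between genotypes, neutrophil granule genes were higher on the VDRmut arrays. Ngp was 4.75-fold higher (log2 2.25 ± 0.24, higher in 4 of 4 pairs), cathelicidin Camp at least 5.67-fold, lactoferrin Ltf 4.85-fold and the calprotectin subunit S100a9 4.17-fold, and Chil1 was 2.48-fold higher. No single probe set passed (0 of 12832 with limma, 361 at an unadjusted p under 0.05, smallest adjusted p 0.24, which was that of Ngp). As a list the neutrophil markers were higher in 14 of 14 members (8 adjusted over the list alone; median 0.90, adjusted p = 9.8e-19, and adjusted p = 0.57 with an estimated correlation). Cell cycle genes were higher in 32 of 33 members (5 over the list alone; median 0.60, adjusted p = 1.1e-21, and adjusted p = 0.63 with an estimated correlation), with the proliferation marker Mki67 2.47-fold and cyclin Ccnb2 2.28-fold higher. Kif23 and Birc5 were Present only on the VDRmut arrays of low actin ratio. The oxidative phosphorylation list had a median of 0.19 (26 of 33 positive, 0 called, adjusted p = 0.0051, and adjusted p = 0.91 with an estimated correlation). For Mki67 the highest signals were 476 and 813.1, on the VDRmut arrays of low actin ratio. Genotype is also mouse and culture here, and the 335 probe sets that passed without both arrays of TNFa alone do not part them.

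**Figure D4:**
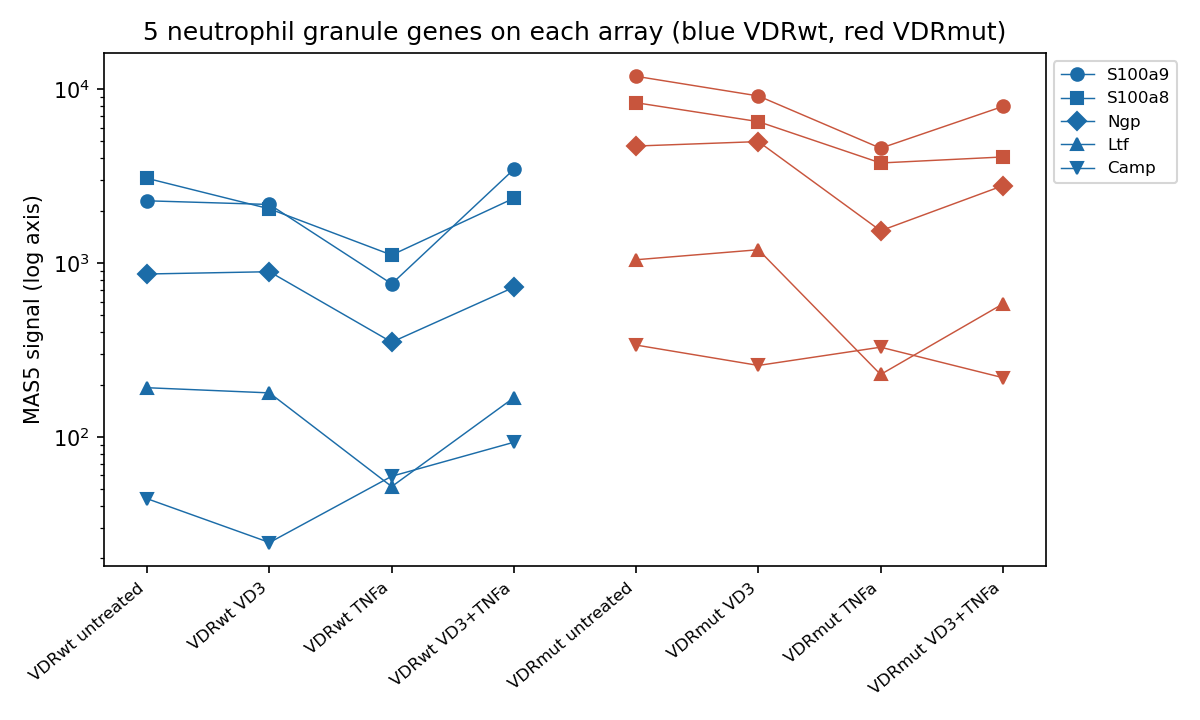
MAS5 signal (log axis) of 5 neutrophil granule genes on each of the 8 arrays, VDRwt in blue and VDRmut in red; each marker shape is a gene and lines join the arrays of a genotype. S100a9 reads 758.5 to 3458 in VDRwt and 4569 to 11840 in VDRmut, and all genes but Camp have their lowest signal of each genotype on the array with TNFa alone.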

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

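Every test of an explanation in this part, the count of other groupings of the arrays, and the fit that separates TNFa with and without VD3 were chosen after the results were seen. Ranges of random lists are their central 95%.

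The TNFa response differed with and without VD3 for 227 probe sets, by the test of that difference itself. The difference in log2 response (with VD3 minus without) was negative for Cxcl1 (-6.31), Bex1 (-6.00), Il12b (-4.11), Pnkd (-4.09), Gsap (-3.95), 2610528A11Rik (-3.92), 4930520O04Rik (-3.59), Net1 (-3.42), Apoe (-3.19), Klrd1 (-2.88), Pfkfb3 (-2.72), Ccr7 (-2.53), Igf1 (-2.32), Gadd45b (-1.95) and Ccl5 (-1.83). It was positive for Olfm1 (5.91), Car4 (5.66), Rnase2a (5.50), Arg1 (4.26), Egln3 (4.11), Cdh1 (3.98), Aldoc (3.76), Scd2 (3.50), Mgl2 (3.32), Slfn1 (3.27), Pdk1 (2.90), Clec10a (2.83), Fdft1 (2.76), Cd177 (2.55), Fcgr1 (2.53), Ccl3 (2.25), Myc (2.20), Fdps (2.12), Il1rn (2.08), Hmgcs1 (2.06), Ifi30 (1.54) and Cycs (1.54). Several of these, Cxcl1 and Olfm1 among them, were not called Present on the dimmer side, so their sizes depend on signals near background. The 5' 18S control signal, which no comparison uses, stood at 9028 on the VDRwt TNFa array and 6847 on the VDRmut TNFa array, above all others.

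The pattern in most of these values is a TNFa response that is smaller with VD3, or of opposite sign, in both genotypes, with exceptions such as Ccl3 (0.22 to 2.72 in VDRwt, 0.43 to 2.43 in VDRmut) and Gsap (-0.27 to -2.16 in VDRwt). Action of VD3 through the DNA binding of its receptor was examined first. The 1372 probe sets that shrank in VDRwt had a median signed change of -1.03 in VDRmut as well. That lies below the central 95% of matched random lists, which began at -0.293 for the 775 higher and -0.0785 for the 597 lower ones. DNA binding alone does not give these VDRmut values, but they cannot decide its part in VDRwt. The TNFa-alone arrays of both genotypes share the high 18S signal, which would give a shared change without VD3 action. In VDRmut, 1 side of this difference is also the untreated and VD3+TNFa arrays of low actin ratio. TNFa genes chosen in both VDRwt pairs did not shrink beyond random lists in VDRmut. Their median was -0.185 for higher ones (random -0.369 to -0.0486, positive with quantile normalization) and 0.391, away from 0, for lower ones. Because they were chosen for a 2-fold response with VD3 as well in VDRwt, they cannot decide the part of DNA binding either. Wholly missing or inactive TNFa in the VD3+TNFa cells is argued against, but only weakly. The lower of the NF-kB list medians with VD3 was 0.357, in VDRmut, at percentile 99.8 of random lists. The central 95% of these lists ended at 0.239. Random lists make no allowance for correlated members. With an estimated correlation, camera gave this list adjusted p = 0.64 for TNFa with VD3. How strongly TNFa acted in these cells was not tested. A different RNA preparation of the arrays with TNFa alone stays open. Such a difference cannot be told apart from a TNFa effect that VD3 blocks, because the pair is the same in both genotypes. The lower 5' 18S signal of that pair was 30.6 times the highest of the other 6 arrays. The separation was smaller on the 3' 18S probe set, with 8511 and 7129 on the pair and 1121 on the VDRwt VD3+TNFa array. A VD3 action without the DNA-binding domain stays open too, untested.

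Regrouping the arrays gave 32 splits for most comparisons. For VD3 by TNFa 1 of the 32 splits, the real one, gave 227 calls and the highest other gave 0. This contrast was picked because the arrays showed that structure, so chance is not excluded by this count. Its count ran from 7 without the VDRmut VD3 array to 470 without the VDRwt untreated array. For the TNFa effect 3 of 32 splits gave as many as the real 29, so chance is not excluded, and the highest other gave 343, several times the real count. That split parts untreated from TNFa arrays where VD3 is absent, which points to a structure of the arrays with TNFa alone. In VDRwt the real split also follows the scan day, and with scan day as a block, which leaves the TNFa effect to the VDRmut arrays, it had 0 calls. For genotype, VD3 by genotype and TNFa by genotype the real count was 0, so all 32, 32 and 31 splits gave as many by construction, and these counts say nothing about chance. The highest other splits gave 68, 227 and 165. Splits with 68 and 227, and 1 of those with 165, put untreated and VD3+TNFa arrays against VD3 and TNFa arrays, a structure of the arrays that is VD3 by TNFa again.

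Neutrophil markers were higher on the VDRmut arrays, with a median log2 genotype effect of 0.90 over 14 members, against -0.083 to 0.171 for the central 95% of matched random lists. Granulocytes among the VDRmut cells are a candidate explanation, since the brightest members Chil3 (0.23), S100a9 (2.06), S100a8 (1.41), Mmp8 (0.40) and Ngp (2.25) were all higher on average. The members rose unevenly, though: Csf3r changed by 0.03, and Chil3, bright on all VDRwt arrays too (3785 to 9827), ran from 6969 to 7770 in VDRmut. No sort of the cells is named in the labels. A genotype effect on the same genes within dendritic cells or their progenitors stays open and was not tested, and genotype, mouse and culture coincide.

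The VDRmut untreated and VD3+TNFa arrays resembled each other (r = 0.9477 across probe sets) more than the untreated array resembled the VD3 array (0.9207). Degraded RNA on both is neither shown nor excluded: the actin ratios of 0.444 and 0.449 were the lowest of the 8, but the Gapdh ratios were 1.15 and 1.28, and the higher lay within those of the other arrays. An exchange of the VDRmut untreated and VD3 arrays cannot be told from the labelled order, since the 84 probe sets that VD3 changed in both VDRwt pairs had a median signed change of -0.0318 in that VDRmut pair, inside the random range of -0.212 to 0.172. The signal of Vdr runs as labelled, higher with VD3 in both VDRwt pairs (0.99 and 1.65 in log2) and read 67.2 against 12.4 (Absent) in this VDRmut pair, which is 1 gene and leaves the question open; no biological explanation was tested.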

How the results depend on the processing

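The fits of TNFa without and with VD3, the scan-day block, the VD3 effect split by genotype in those fits and the fits without pairs of arrays were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each condition has 1 array and a block of replicate numbers would hold all 8 in 1 block; the genotype term already compares treatments within a genotype. TNFa by genotype could not be fitted without pairs of arrays, nor TNFa without VD3 and VD3 by TNFa without both TNFa-alone arrays. Without a pair of arrays the planned model has 1 residual degree of freedom, so its counts there are not comparable with those over all 8. Deposited scaling, quantile normalization, Present on 4 arrays and the series matrix left each count of calls within 1.5 times its value. A floor also ended calls of genes with no signal under it, such as Clec4e (log2 2.04 either way). For these changes the cause was not tested.

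With a floor of 50 the calls became 0 for the TNFa effect, 512 for the TNFa effect without VD3, 1 for the TNFa effect with VD3 and 10 for VD3 by TNFa. With no filter they were 2 (TNFa), 6 (with VD3) and 56 (VD3 by TNFa), and without a trend 5, 8 and 37. Without the low-actin VDRmut pair they were 0, 168 and 144. Without the TNFa-alone pair they were 1313 for TNFa, 202 for VD3 in VDRmut, 23 for VD3 by genotype and 335 for genotype. With scan day as a block, which coincides with TNFa in VDRwt and so leaves the TNFa effect to VDRmut, they were 0 (TNFa), 341 (without VD3), 1 (with VD3) and 136 (VD3 by TNFa). Main effects only gave 412 for TNFa, VDRwt arrays only 0 and VDRmut arrays only 7. A VD3 effect split by genotype gave 10 for TNFa with VD3. Leaving out 1 array gave 0 to 6 for TNFa, 365 to 1089 without VD3, 0 to 692 with VD3 and 7 to 470 for VD3 by TNFa, where a condition without its array is assumed to vary like the others. VD3 in VDRwt and TNFa by genotype stayed at 0 in every fit run.

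At log2(1.5), the VD3 change of the TNFa response passed in 5441 probe sets in VDRwt. For the VD3 change of the TNFa response, VDRmut had 6958. For the VD3 change of the TNFa response, same direction in both genotypes, there were 2765. At log2(3) these were 977, 1700 and 362. For VD3 on TNFa genes, higher in VDRwt, the median was -0.147 with a floor and -0.125 at Present on 4 arrays. For VD3 on TNFa genes, lower in VDRwt, it was -0.82 with quantile normalization, -0.69 with a floor and -1.8 at log2(3). For VD3 on TNFa genes, higher in VDRmut, it reversed to 0.0202 with quantile normalization and 0.0252 with a floor, and was -0.538 at log2(3). For VD3 on TNFa genes, lower in VDRmut, it was 0.233 at log2(1.5) and 0.847 at log2(3).

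With an estimated correlation the 20 list calls of the planned contrasts became 0, and so did the 20 of the split TNFa fits. Quantile normalization ended 1 list call for TNFa without VD3 and 1 for VD3 by TNFa. The mean of a gene's probe sets ended 1 for VD3 in VDRwt. Across the alternatives, 8 values of uncalled lists became calls. Of the named genes, 129 called changes gave 1677 values under alternatives. Of these 1154 kept their call, 523 lost it with the same direction, and 30 changes kept it throughout. The values under deposited scaling and the series matrix are nearly those of the main fit, so the calls kept there say nothing about robustness. The 31 uncalled ones stayed so in all 403 values. No named gene and no called list reversed. For uncalled lists a change of direction was not recorded.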

Other observations

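All values here come from the fit that separates TNFa with and without VD3, chosen after the data were seen, and concern TNFa without VD3 unless stated; lists not described in the results follow. Of the chemokine list 4 of 17 rose and 2 fell (6 and 4 adjusted over the list alone; median 0.33, adjusted p = 0.19), with the dendritic cell chemokine Ccl22 higher 3.23-fold. Antigen presentation genes moved little as groups: of MHC class II genes 1 of 17 rose and 2 fell (1 and 2 over the list alone; median 0.15, mean -0.019, adjusted p = 0.82), the peptide-loading chain H2-DMa by 2.94-fold and the lysosomal reductase Ifi30 by 2.5-fold, and of MHC class I genes 0 of 17 changed (0 over the list alone; median -0.21, adjusted p = 0.55). The interferon response list had 5 of 33 lower and 3 higher (6 and 3 over the list alone; median -0.16, adjusted p = 0.20), with Irf7 (4.45-fold), Oasl2 (4.27-fold) and Ifitm3 (3.59-fold) lower. Genes linked to tolerance went both ways, 5 of 27 higher and 4 lower (8 and 7 over the list alone; median 0.0073, adjusted p = 0.90): Cd200 rose 6.24-fold and the ubiquitin editor Tnfaip3 3.76-fold while Arg1 fell. The heat shock and stress list had 3 of 29 higher and 2 lower (3 and 2 over the list alone; median 0.28, adjusted p = 0.19), with the inducible chaperone Hspa1b higher 9.17-fold and Myc lower at least 4.78-fold.

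Among marker lists of other cell types, only the neutrophil one passed. Of 14 macrophage markers 2 rose and 3 fell (the same counts over the list alone; median -0.18, adjusted p = 0.69): Apoe rose 3.88-fold and Ms4a7 by 1.84 ± 0.22 on the log2 scale, and the high-affinity Fc receptor Fcgr1 fell 4.93-fold. For Apoe the TNFa response turned from 1.8 and 2.12 in log2 without VD3 to -1.12 and -1.35 with it. Of 4 mast cell and basophil markers 1 rose, Cpa3 (median 0.78, adjusted p = 0.16); of 7 T and NK cell markers 1, Klrd1 (0.31, adjusted p = 0.55); of 6 B cell markers 1, Blnk (0.022, adjusted p = 0.55); each of these 3 counts was 1 over the list alone. Of 4 erythroid markers the metallothionein Mt2, which is not specific to that lineage, fell (-0.10, adjusted p = 0.63; 1 over the list alone), and of 7 plasmacytoid dendritic cell markers Irf7 fell (0.15, adjusted p = 0.98; 1 over the list alone). Of 9 progenitor markers 2 rose, Sox4 among them (0.057, adjusted p = 0.72; 2 higher and 2 lower over the list alone), and of 8 stromal markers Vcam1 rose and fibronectin Fn1 fell (0.14, adjusted p = 0.97; 1 and 2 over the list alone). The vitamin D response list had 2 of 13 lower, Trem1 (117.7 to an Absent 12.7 in VDRwt, Absent throughout in VDRmut) among them (-0.45, adjusted p = 0.55; 2 over the list alone). With an estimated correlation the adjusted p of the lists described so far ran from 0.62 to 0.99, and that of the neutrophil list was 0.46.

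With 1 pair of arrays per genotype, the dendritic cell maturation list had a median change of the TNFa response by VD3 of -0.889 in VDRwt (central 95% of random lists -0.216 to 0.308) and -0.535 in VDRmut (-0.212 to 0.428). The glycolysis list had 1.32 in VDRwt (-0.268 to 0.413) and 0.86 in VDRmut (-0.205 to 0.572). These ranges describe these arrays only, and in all 4 cases the array with TNFa alone carries the high 18S signal.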
